A study of Nicotiana tabacum with 12 samples.

How the data were processed

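Leaves of field-grown tobacco (Nicotiana tabacum) were sampled, per the labels, from a randomized complete block trial with 4 nitrogen levels: none (T1, 0 kg per hectare), deficient (T2, 60 kg), standard (T3, 105 kg) and excess (T4, 150 kg). Per the labels, every plot of 66.7 m2 received 105 kg of phosphorus and 210 kg of potassium per hectare, with 70% of the fertilizer given before planting and 30% as topdressing. Each level had 3 libraries, 12 in all, and the table held 0 columns of other samples. Values deposited by the authors are FPKM, fragments per kilobase of gene model and per 1e+06 reads, for 47216 gene models of the Nitab4.5 series. The aligner and the read counter are not given in the sources used here. The only genome build in the submitters' notes is mm10, a mouse build, while the row identifiers are tobacco gene models. Of these identifiers, 0 were found among the 79372 entries of the RefSeq gene table at hand, so no genome positions are given. Gene names are the descriptions deposited with the table, present for 46616 genes, and often name a protein of a related species.

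Low values of the deposited FPKM table are whole multiples of 1 step per gene and library, from which the reads behind each value and the library totals were worked out (python 3.11.15, numpy 2.4.6, pandas 2.3.3). The totals lay between 12347143 reads (T4 replicate 2) and 34470685 (T4 replicate 1). In the shallowest library 1 read on a gene of 1200 bases, the median inferred length, equals 0.0675 FPKM. Among genes with at least 200 reads over the 12 libraries, counting error was small beside the differences between libraries of 1 level. Genes with fewer reads were not covered. A chi-square of replicate reads per degree of freedom was 38.3 at the lowest and 140 at the highest of the replicate pairs, where counting error alone gives about 1. Differences between plots and those of sample preparation cannot be told apart by it.

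Genes with an FPKM of at least 1 in at least 3 libraries were tested, 34369 in all. Values were used as log2(FPKM + 1), which understates fold changes of genes near 1 FPKM. The tests were limma's moderated tests (limma 3.58.1, R 4.3.3, eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A single fit with 1 mean per nitrogen level gave 5 pairwise comparisons and an F-test over the 4 levels. A fit with the nitrogen dose as a numeric term gave a slope, written as log2 per 100 kg for genes and over the whole range of 150 kg for lists of genes. The replicate number was not used as a block, because the labels do not say that it stands for a field block. The p-values of single genes measure the spread between these libraries of 1 trial. For the slope that spread includes any departure of the level means from a straight line.

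Gene lists were written from words in the descriptions before the data were examined, as were the comparisons, the tests and most alternatives: 33 lists of functions and 7 of cell type markers, 40 in all, each with at least 5 genes. For length, some lists that passed camera are not in the text, among them cytosolic ribosome and carotenoid synthesis genes. The lists were tested with limma's camera at its preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry. Camera compares the genes of a list with all other genes, so its p-values rest on the spread among genes and the correlation used. The named genes follow a rule also fixed before. In the comparisons with T3 and in T4 against T1 it takes up to 8 rising and 8 falling genes past the threshold with no overlap between groups, a mean of at least 5 FPKM in the higher group and an informative description, and 4 of each for T2 against T1 and for the dose. Where fewer than 3 passed in a direction, the 3 with the smallest p under the same rule for expression and description are named. It adds up to 2 rising and 2 falling members of each list that passed camera, of which some are left out for length, and the most abundant gene of 9 nitrogen-related descriptions whatever its change. Genes outside this rule are said to have been chosen after their values were seen.

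The tests were also run on simulated data with 200 changed genes and the depths and spread of these libraries. For T1 against T3, 7.46% of the 2-fold, 55.2% of the 4-fold and 71.2% of the 8-fold changes were recovered, with 3 false calls among 92. For the dose, 19.4%, 61.2% and 84.8% were recovered, with 8 false calls among 118. A list shifted 2-fold in simulated data had an adjusted p of 7.74e-67 with camera, and 0 of the 39 other lists passed. Each gene was drawn independently, so unshifted genes of a list did not move together. In the deposited data the estimated correlation within a list reached 0.586, and random assignments of the doses called a median of 11 lists. The simulation therefore says nothing on false list calls in these data, and its false gene calls hold only for independent genes.

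Alternatives chosen before were a pseudocount of 0.1, no filter or a filter of 5 FPKM, rescaling to TPM, quantile normalization, median-ratio scaling, a replicate block, no mean-variance trend, only the 2 groups compared, a 2-fold minimum, the dose as a rank, and leaving out each library in turn. Chosen after seeing the data were limma voom on the recovered reads, library weights, principal component 1 as a covariate, and leaving out the 2 shallowest libraries. Figures were drawn with matplotlib 3.10.9. Putrescine N-methyltransferase was under the expression filter and was not tested.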

Results

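The largest axis of the 12 leaf libraries did not follow the nitrogen level. Principal component 1 of log2(FPKM + 1) held 26.7% of the variance, and 10.03% of it lay between nitrogen levels, against 27.3% by chance. Component 2 held 16.9%, with 38.3% of it between nitrogen levels. Only 1 of the 12 libraries had a library of its own level as its closest by Spearman correlation. Correlations ran from 0.904 to 0.954 within levels and from 0.887 to 0.971 between levels. Libraries with the same replicate number did not go together either: the correlations of their deviations from the group means ran from -0.36 to 0.41. The F-test over the 4 levels (limma) called 0 genes, with 1027 genes at an unadjusted p under 0.05 where 1718 are expected by chance and 920 by voom.

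**Figure D1:**
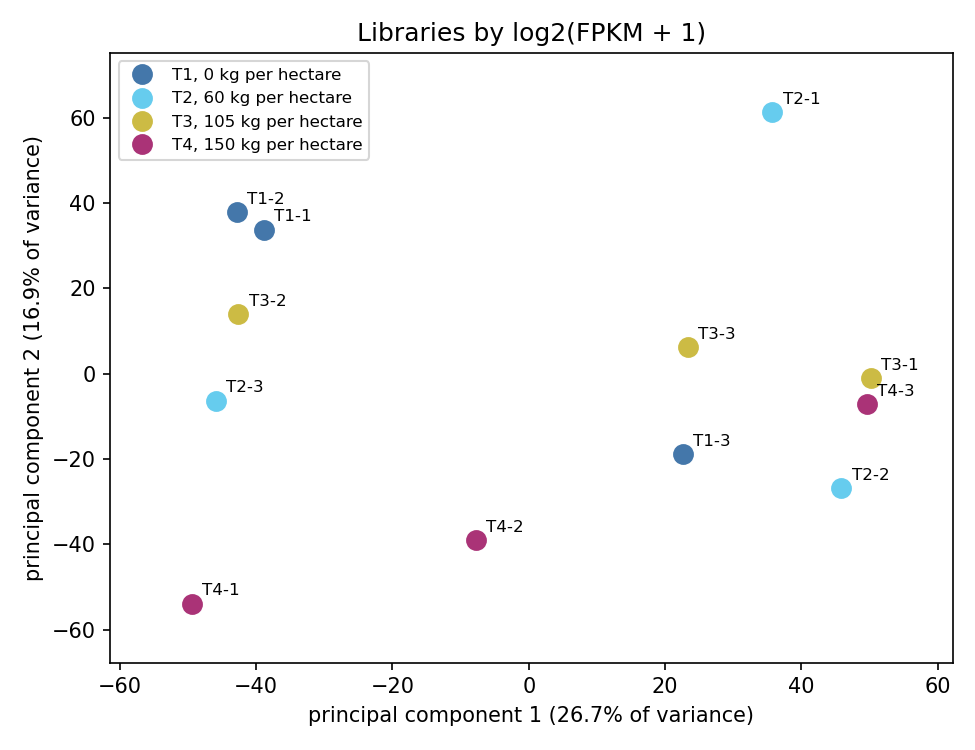
The 12 libraries on the first and second principal components of log2(FPKM + 1), 1 point per library, labelled by nitrogen level and replicate. Libraries of each of the 4 levels lie on both sides of 0 on principal component 1.

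The genes that passed the test of the nitrogen dose included 4 pathogenesis-related genes of the 126 tested. The acidic pathogenesis-related gene PR-1A (Nitab4.5_0003771g0010), which codes for a secreted antimicrobial protein and serves as a marker of salicylate defence, had a mean of 784 ± 56.6 FPKM without nitrogen (SD, n = 3), 1315 ± 111 at the deficient level, 1940 ± 124 at the standard level and 2757 ± 816 at the excess level. Snakin-2 (Nitab4.5_0000980g0290), a cysteine-rich antimicrobial peptide, had 143 ± 18.2, 377 ± 20.6, 426 ± 28.8 and 741 ± 342 FPKM. A gene described as the basic form of PR-1 (Nitab4.5_0001477g0080) had 1.57 ± 0.887, 8.70 ± 6.88, 11.8 ± 2.30 and 57.5 ± 56.4 FPKM, and a similar gene (Nitab4.5_0007488g0040) had 2.65 ± 1.42, 10.3 ± 3.66, 19.5 ± 8.41 and 58.5 ± 59.5 FPKM. Reads shared between close copies such as these cannot be separated in FPKM values. The tonoplast aquaporin TIP1-1 (Nitab4.5_0011193g0010), a water channel of the vacuole, had 2.00 ± 0.675, 5.80 ± 1.83, 11.8 ± 4.05 and 29.5 ± 27.2 FPKM. At the excess level the SD of TIP1-1, Nitab4.5_0001477g0080 and Nitab4.5_0007488g0040 was close to the mean, so these means are uncertain.

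The dose slope passed the threshold for 10 genes, all higher with more nitrogen (limma), with 1841 genes at an unadjusted p under 0.05 where 1718 are expected by chance. With the doses assigned to the libraries at random, between 357 and 6144 genes had such a p, so 1841 lies within what chance gives. Voom called 5 genes, 4 of them higher and 4 shared with the 10. Slopes per 100 kg were 2.63 ± 0.38 (SE) for Nitab4.5_0001477g0080, 2.38 ± 0.34 for Nitab4.5_0007488g0040, 1.98 ± 0.31 for TIP1-1, 1.42 ± 0.21 for snakin-2 and 1.19 ± 0.15 for PR-1A. Adjusted p-values were 0.0462 for TIP1-1 and 0.0414 for the other 4. The remaining 5 genes were chosen after their values were seen. A thaumatin-like gene (Nitab4.5_0000360g0100), of another antifungal family, had means of 174, 322, 381 and 539 FPKM. The probable sulfate transporter 3.4 (Nitab4.5_0002438g0030) had 1.52, 4.22, 7.59 and 8.86 FPKM, and a WAT1-related membrane protein (Nitab4.5_0004692g0040) had 9.39, 11.5, 17.4 and 20.9 FPKM. An uncharacterized gene (Nitab4.5_0000151g0310) and a hypothetical one (Nitab4.5_0003604g0050) had slopes of 0.72 and 2.08. The calls were close to the threshold: 0 genes passed with the replicate number as a block (smallest adjusted p 0.121), with quantile normalization or without a filter on low values. Leaving out 1 library gave 0 genes without T1 replicate 1, 2 or 3, T2 replicate 1, T3 replicate 1, 2 or 3, or T4 replicate 2, while 2 passed without T2 replicate 2, 1 without T4 replicate 1, 3 without T4 replicate 3 and 11 without T2 replicate 3. All 10 slopes were positive in each of these fits. The genes were picked for their rise in the same libraries, so this sign says little. Slopes without 1 library ran from 1.10 to 1.32 for PR-1A, from 1.30 to 1.67 for snakin-2 and from 2.21 to 2.84 for Nitab4.5_0001477g0080. They ran from 1.99 to 2.57 for Nitab4.5_0007488g0040 and from 1.63 to 2.28 for TIP1-1.

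**Figure D2:**
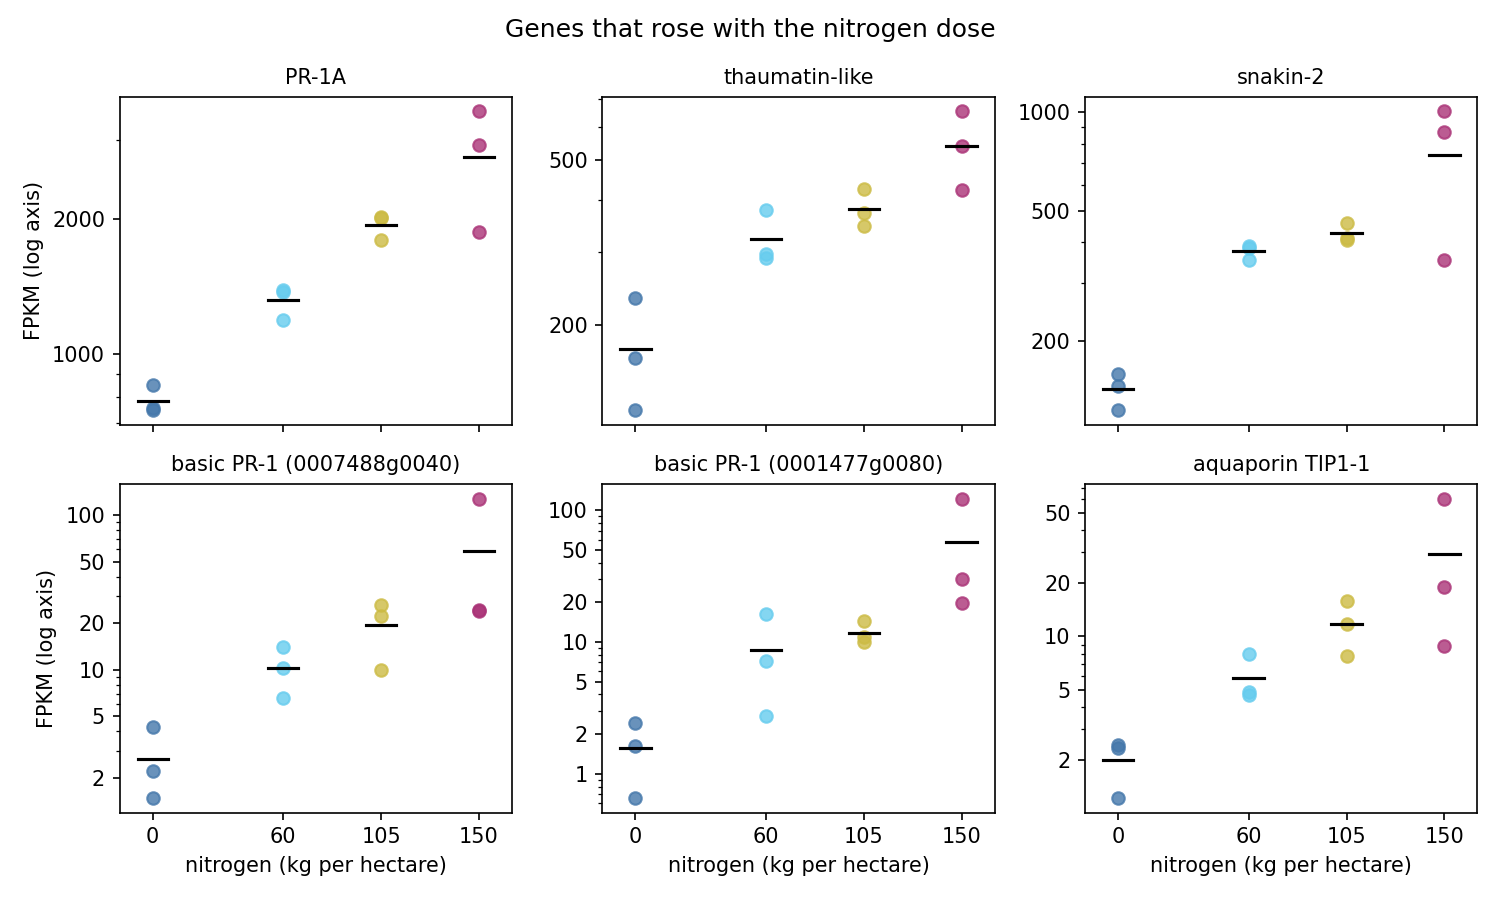
FPKM on a log axis against the nitrogen dose in kg per hectare for 6 of the genes that rose with the dose, 1 point per library, with a bar at the mean of 3 libraries. The 3 libraries without nitrogen lie below all 9 others in each of the 6 genes.

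No gene passed the test as lower with the dose. Of the 3 with the smallest p in that direction, CP12-2 (Nitab4.5_0008277g0010), a small protein that binds Calvin cycle enzymes in the dark, had 280 ± 34.7, 196 ± 85.0, 143 ± 25.5 and 94.4 ± 41.9 FPKM (slope -1.07 ± 0.20, adjusted p = 0.188). The biotin carboxyl carrier protein of acetyl-CoA carboxylase (Nitab4.5_0000620g0080), of fatty acid synthesis, had a slope of -0.62 ± 0.13 (adjusted p = 0.228), and the DNA-binding protein OSB2 (Nitab4.5_0000187g0180) had -0.48 ± 0.10 (adjusted p = 0.243).

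Genes of nitrogen uptake and assimilation did not pass the dose test. Nitrate reductase (Nitab4.5_0002857g0010), the first enzyme of nitrate assimilation, had 452 ± 77.9, 276 ± 79.8, 357 ± 99.3 and 286 ± 83.0 FPKM (slope -0.36 ± 0.20, adjusted p = 0.949). Nitrite reductase (Nitab4.5_0018347g0010) had 192 ± 67.3, 97.1 ± 9.92, 127 ± 49.3 and 98.4 ± 17.7 FPKM (slope -0.51 ± 0.22, adjusted p = 0.903; -0.31 without T1 replicate 1). Plastid glutamine synthetase (Nitab4.5_0000059g0010), which fixes ammonium, had 239, 193, 176 and 211 FPKM, and ferredoxin-dependent glutamate synthase (Nitab4.5_0000415g0090) had 99.5, 89.4, 91.4 and 93.6 FPKM. Asparagine synthetase (Nitab4.5_0000102g0010) had 14.3, 21.9, 18.2 and 14.9 FPKM. The most abundant small subunit gene of Rubisco (Nitab4.5_0001382g0020), whose reads are shared with close copies, had 2115, 1763, 1590 and 1818 FPKM. The nitrate transport partner NRT3.1-like (Nitab4.5_0008037g0060) had 57.2, 58.2, 57.3 and 50.2 FPKM, and ammonium transporter 1 member 1 (Nitab4.5_0003474g0010) had 163, 140, 144 and 107 FPKM. Over the 37 tested genes of the nitrogen assimilation list the median slope was -0.01 and the mean 0.08, and camera gave the direction down (adjusted p = 0.987). The nitrate transport list (69 genes) had a median of 0.14 (adjusted p = 0.301; 0.08 without T4 replicate 1 and 0.0079 without a filter on low values), with 1 gene past the threshold adjusted over the list alone and 0 over all genes.

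Among gene lists, the pathogenesis-related list (126 genes tested) had a median slope of 0.31 over the dose range, with 90 members higher and 36 lower, and 0.20 without T1 replicate 2 and 0.09 without a filter on low values. With an estimated correlation its adjusted p was 0.0887, and fry gave 0.0477 for movement in 1 direction and 4.34e-06 for change in either direction. Adjusted over the list alone, 21 of its genes passed, against 4 over all genes. Neither fry nor the count over the list alone was run on random assignments of the doses, so these values do not exclude chance. The phosphate starvation list (90 genes), of genes that plants use to save and recover phosphate, had a median of 0.36 (68 higher, 22 lower; 0.18 without a filter on low values), with 7 genes adjusted over the list alone and 0 over all genes; adjusted p = 0.38 with an estimated correlation. Its members glycerophosphodiester phosphodiesterase GDPD1 (Nitab4.5_0002172g0020) and purple acid phosphatase 3-like (Nitab4.5_0000926g0140) had slopes of 2.16 ± 0.51 and 1.79 ± 0.43 (both with an adjusted p of 0.335). Photosystem and light-harvesting genes (154) had a median of -0.42, 146 of them lower (adjusted p = 0.38 with an estimated correlation), and -0.21 without T1 replicate 1. Chloroplast ribosome genes (134) had -0.32 (adjusted p = 0.38 with an estimated correlation). The glandular trichome markers (13 genes) had -0.53, with 12 lower (adjusted p = 0.0887 with an estimated correlation), and ran from -0.88 with a pseudocount of 0.1 to -0.15 without a filter on low values. The organelle-encoded and ribosomal RNA markers (43 genes, mostly for proteins that process ribosomal RNA) had -0.14 with 32 lower (adjusted p = 0.38 with an estimated correlation), and -0.06 without T1 replicate 3. At the preset correlation camera called 15 of the 40 lists for the dose, 7 up and 8 down. With an estimated correlation 0 lists passed in this or any other comparison.

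**Figure D3:**
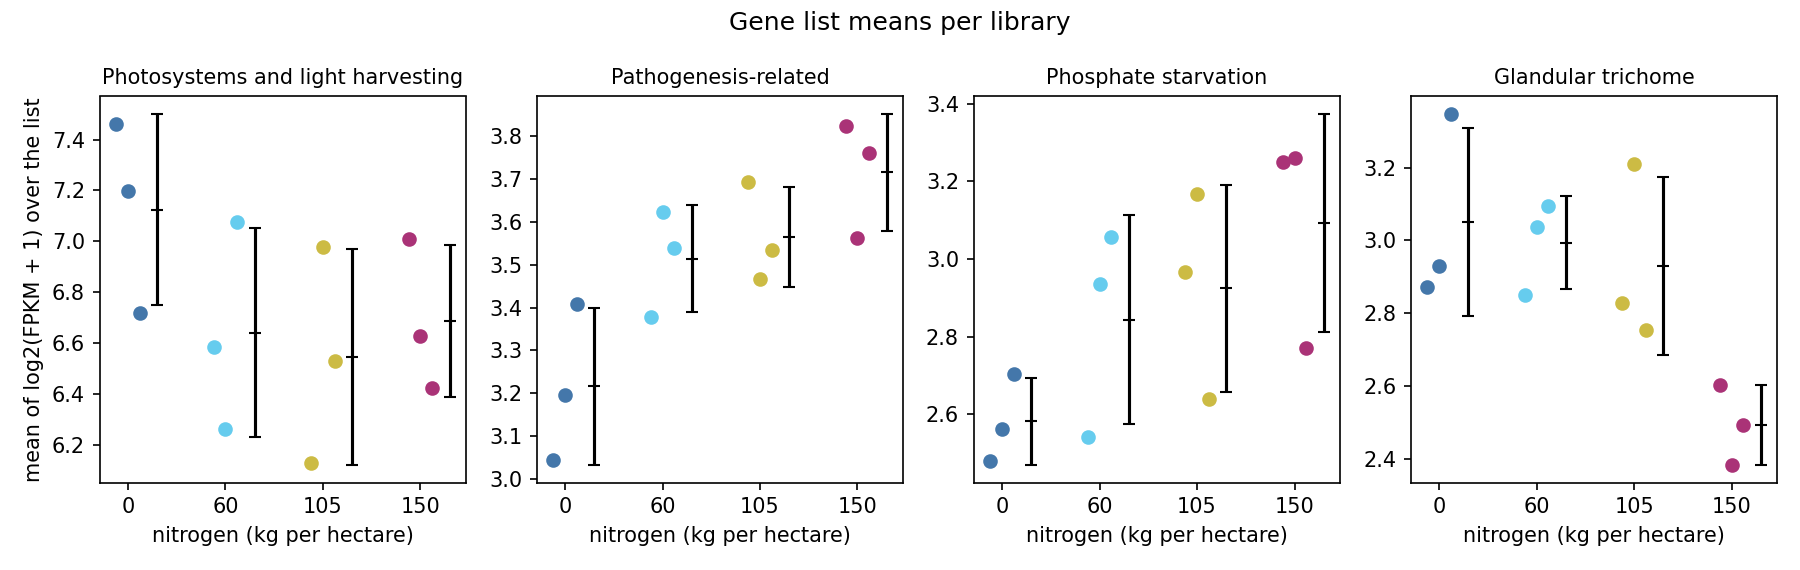
Mean log2(FPKM + 1) over the genes of 4 lists in each library, by nitrogen dose in kg per hectare, with the mean and SD of each level beside its 3 points. Photosystem means overlap between all levels, from 6.13 to 7.46 over the 12 libraries.

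Without nitrogen, no gene passed the test against the standard level, and a light-harvesting gene was among those with the smallest p. Chlorophyll a-b binding protein 40 (Nitab4.5_0000592g0360) of the light-harvesting antenna had 219 ± 25.1 FPKM in T1 and 96.6 ± 28.9 in T3 (n = 3 each; log2 difference 1.21 ± 0.27 SE). The plastid peptidyl-prolyl isomerase FKBP17-2 (Nitab4.5_0008639g0010) had 6.01 ± 1.00 and 1.32 ± 0.923 FPKM (1.65 ± 0.32). XERICO (Nitab4.5_0001229g0050), a ubiquitin ligase that raises abscisic acid, had 32.9 ± 9.62 and 13.3 ± 4.63 FPKM (1.26 ± 0.29). Each of these had an adjusted p of 0.999. The lowest p on the other side belonged to exportin-7 (Nitab4.5_0002094g0070; -1.77 ± 0.28) and to the metal-binding isoprenylated proteins Nitab4.5_0002366g0070 (-1.45 ± 0.25) and Nitab4.5_0000465g0010 (-1.20 ± 0.21), all with an adjusted p of 0.721.

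For T1 against T3, limma called 0 genes, with 1209 at an unadjusted p under 0.05 (438 higher, 771 lower) and 0 past the threshold by voom, which had 1259 at an unadjusted p under 0.05. The 3 libraries of each level did not overlap for 9.72% of genes, against 10% by chance. PR-1A differed by -1.31 ± 0.26 and the thaumatin-like gene Nitab4.5_0000360g0100 by -1.16 ± 0.26. The Rubisco small subunit gene Nitab4.5_0020038g0010 had 482 FPKM in T1 and 248 in T3 (1.02 ± 0.39). The class IV heat shock protein Nitab4.5_0003818g0040 had 0.303 and 19.1 FPKM (-3.23 ± 1.16), and purple acid phosphatase 3-like had 0.502 and 6.77 FPKM (-2.23 ± 0.70). Camera called 15 lists, 7 up and 8 down. Photosystem and light-harvesting genes had a median of 0.63, with 146 of 154 higher in T1 (adjusted p = 0.385 with an estimated correlation), while their library means overlapped (6.72 to 7.46 in T1, 6.13 to 6.98 in T3). The organelle-encoded and ribosomal RNA markers had 0.10, with 33 of 43 higher (adjusted p = 0.46 with an estimated correlation), and 0.04 without T3 replicate 1. Chloroplast ribosome genes had 0.39 (adjusted p = 0.385 with an estimated correlation), chlorophyll synthesis genes 0.37 (39 genes; adjusted p = 0.385 with an estimated correlation) and carbon fixation genes 0.43 (53 genes; adjusted p = 0.414 with an estimated correlation). Pathogenesis-related genes had -0.27 with 95 of 126 lower, 3 past the threshold adjusted over the list alone and 0 over all genes (adjusted p = 0.385 with an estimated correlation). Phosphate starvation genes had -0.26 (adjusted p = 0.752 with an estimated correlation). Heat shock and chaperone genes (221) had a median of -0.11 and a mean of -0.35 (adjusted p = 0.855 with an estimated correlation). Without T3 replicate 1 the medians were 0.38 for photosystem, 0.22 for chloroplast ribosome, 0.23 for chlorophyll synthesis, 0.15 for carbon fixation and -0.16 for pathogenesis-related genes. The last was -0.17 without T1 replicate 1 and -0.41 without T1 replicate 3, where heat shock genes had -0.06 and -0.20, and phosphate starvation genes had -0.17 without T3 replicate 2. Without a filter on low values pathogenesis-related genes had -0.11 and the organelle markers 0.06. With principal component 1 as a covariate the medians were 0.37 for photosystem, 0.21 for carbon fixation and -0.18 for pathogenesis-related genes.

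The deficient level had no gene past the threshold against the standard level, which does not show that the leaves were alike. The genes with the smallest p among the higher ones were GLC8 (Nitab4.5_0001508g0020), a phosphatase regulator, with 8.98 ± 1.05 FPKM in T2 and 4.49 ± 0.386 in T3 (log2 difference 0.86 ± 0.18 SE, n = 3), the receptor kinase ERL2 (Nitab4.5_0002786g0100; 1.28 ± 0.31) and phosphoglycerate mutase-like protein 4 (Nitab4.5_0000310g0250; 1.17 ± 0.35). Among the lower ones were a beta-1,3-galactosyltransferase 7-like gene (Nitab4.5_0006278g0020; -0.90 ± 0.22), the metal-binding protein Nitab4.5_0000465g0010 (-0.83 ± 0.21) and the vesicle trafficking subunit Nitab4.5_0005420g0050 (-0.73 ± 0.20). Limma called 0 genes for T2 against T3, with 360 at an unadjusted p under 0.05 (175 higher, 185 lower) and 0 past the threshold by voom, which had 241 at an unadjusted p under 0.05. Groups did not overlap for 4.18% of genes, against 10% by chance. Cytokinin genes (64) had a median of -0.22 with 53 lower (adjusted p = 0.389 with an estimated correlation). Among them ARR9-like (Nitab4.5_0008001g0030), a response regulator of cytokinin signalling, had 78.1 ± 16.8 FPKM in T2 and 122 ± 39.0 in T3 (-0.62 ± 0.30; -0.38 without T3 replicate 2). The WAT1-related gene Nitab4.5_0004692g0040 differed by -0.59 ± 0.18. Chloroplast ribosome genes had a median of 0.19 and photosystem genes 0.10 (each with adjusted p = 0.966 with an estimated correlation), and amino acid transport genes (98) had -0.13 (adjusted p = 0.966 with an estimated correlation). The photosystem median turned negative, to -0.11 without T2 replicate 3 and -0.09 without T3 replicate 1, and was 0.28 without T2 replicate 2 and 0.29 without T3 replicate 2. In the first 3 of these fits the chloroplast ribosome median was 0.02, 0.0040 and 0.38. The amino acid transport median ran from -0.26 (without T2 replicate 2) to -0.07 (without T3 replicate 1), and was -0.07 also without T3 replicate 2, -0.07 without T2 replicate 1 and -0.08 without T2 replicate 3. Without a filter on low values it was -0.03, and the cytokinin median -0.11. The photosystem II D1 gene Nitab4.5_0003961g0020 had 168 ± 139 FPKM in T2, with 328 in T2 replicate 3 alone, and 78.7 ± 30.3 in T3 (0.84 ± 0.47; 0.20 without T2 replicate 3 and 1.31 without T2 replicate 2). Camera called 4 lists at the preset correlation, 2 up and 2 down.

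At the excess level no gene passed the test against the standard level. The named genes with the smallest p on the higher side were 3 enzymes. ATP sulfurylase 1 (Nitab4.5_0000977g0040), the entry enzyme of sulfate assimilation, had 13.1 ± 7.47 FPKM in T4 and 2.60 ± 1.46 in T3 (log2 difference 1.85 ± 0.46 SE, n = 3). S-adenosylmethionine synthase 2 (Nitab4.5_0004665g0010) had 148 ± 41.1 and 69.8 ± 10.4 FPKM (1.04 ± 0.25), and gamma-glutamyl peptidase 5-like (Nitab4.5_0005908g0080) had 9.35 ± 4.61 and 2.32 ± 1.5 FPKM (1.64 ± 0.37). On the lower side were the RNA-binding protein LSM8 (Nitab4.5_0012011g0030; -1.08 ± 0.26), GATA transcription factor 15-like (Nitab4.5_0005180g0060; -0.99 ± 0.25) and the transcriptional activator TAF-1-like (Nitab4.5_0002262g0160; -0.83 ± 0.21). All 6 had an adjusted p of 1.00. Limma called 0 genes for T4 against T3, with 1122 at an unadjusted p under 0.05 (412 higher, 710 lower) and 0 past the threshold by voom, which had 1010 at an unadjusted p under 0.05. Groups did not overlap for 7.68% of genes, against 10% by chance. Cell wall expansion genes (200) had a median of 0.25 with 134 higher (adjusted p = 0.772 with an estimated correlation), among them expansin-A4-like (Nitab4.5_0004599g0080; 1.78 ± 0.50). Markers of the vascular secondary wall (38) had 0.18 with 24 higher, and glandular trichome markers -0.37 with 11 of 13 lower (each with a camera adjusted p of 0.0149, and adjusted p = 0.772 with an estimated correlation). T4 replicate 1 had the highest library mean of cell wall expansion (3.69) and vascular genes (3.06), and without it the vascular median was 0.06. The vascular median was 0.11 without T3 replicate 2 and 0.30 without T3 replicate 3. The trichome median was -0.56 without T3 replicate 1, -0.24 without T3 replicate 2 and -0.02 without a filter on low values. Without that filter the medians were 0.06 for cell wall expansion, 0.05 for vascular, 0.06 for auxin and 0.06 for pathogenesis-related genes. Auxin genes (173) had 0.11 and pathogenesis-related genes 0.15 (each with adjusted p = 0.772 with an estimated correlation), among them the SAUR-like gene Nitab4.5_0002096g0170 (1.73 ± 0.51, and 1.00 without T4 replicate 2; 32.3 FPKM in that library against 7.98 and 4.94 in the other T4 libraries) and basic endochitinase (Nitab4.5_0000188g0340; 36.0 ± 9.79 and 20.03 ± 4.55 FPKM). Heat shock and chaperone genes had a median of -0.13 and a mean of -0.40 (adjusted p = 0.772 with an estimated correlation), and the dnaJ chaperone Nitab4.5_0004359g0040 had 42.4 ± 14.2 and 100 ± 16.7 FPKM. Photosystem genes had 0.17 (adjusted p = 0.873 with an estimated correlation), and camera's direction for them turned to down without T3 replicate 1. Without that library the photosystem median was 0.0037 and the pathogenesis-related one 0.22. Without T4 replicate 1 the medians were 0.12 for cell wall expansion, 0.02 for auxin and 0.02 for photosystem genes. Without T3 replicate 2 they were 0.12 for cell wall expansion, 0.07 for pathogenesis-related and 0.36 for photosystem genes, and without T4 replicate 3 they were -0.25 for heat shock, 0.19 for auxin, 0.09 for pathogenesis-related and 0.33 for photosystem genes. Nicotine and alkaloid synthesis genes (13) had a median of 0.26 with 9 higher (adjusted p = 0.772 with an estimated correlation). Camera called 14 lists, 10 up and 4 down.

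Between the ends of the range, defence genes were among those with the smallest p. Excess against no nitrogen gave log2 differences of 1.84 ± 0.25 for the metal-binding protein Nitab4.5_0002366g0070, 2.24 ± 0.32 for snakin-2, 1.77 ± 0.26 for PR-1A and 4.13 ± 0.62 for the basic PR-1 gene Nitab4.5_0001477g0080 (SE, n = 3; adjusted p = 0.101 for each). On the lower side were CP12-2 (-1.64 ± 0.34, adjusted p = 0.344), the amino acid enzyme threonine aldolase 1 (Nitab4.5_0003780g0010; -1.06 ± 0.22, adjusted p = 0.344) and LSM8 (-1.13 ± 0.26, adjusted p = 0.489). Limma called 0 genes for T4 against T1, with 1706 at an unadjusted p under 0.05 (1025 higher, 681 lower) and 0 past the threshold by voom, which had 1609 at an unadjusted p under 0.05. Groups did not overlap for 9.67% of genes, against 10% by chance. Without T4 replicate 3, 6 genes passed. Pathogenesis-related genes had a median of 0.37 with 91 of 126 higher, 19 past the threshold adjusted over the list alone and 0 over all genes (adjusted p = 0.112 with an estimated correlation), and fry gave 1.15e-04 for change in either direction. Neither fry nor the count over the list alone was run on other splits of these libraries. Phosphate starvation genes had 0.39 (adjusted p = 0.425 with an estimated correlation), with GDPD1 (Nitab4.5_0002172g0020) at 44.9 ± 19.8 FPKM in T4 and 3.71 ± 3.18 in T1. Photosystem genes had -0.39 with 144 of 154 lower (adjusted p = 0.51 with an estimated correlation), among them chlorophyll a-b binding protein 6A (Nitab4.5_0001448g0030; -0.74 ± 0.20). The organelle-encoded and ribosomal RNA markers had -0.09 with 35 of 43 lower (adjusted p = 0.464 with an estimated correlation), -0.06 without T1 replicate 3, -0.16 without T1 replicate 1 and -0.21 without T4 replicate 3, and camera did not call them without T4 replicate 1. Chlorophyll synthesis genes had -0.29 (adjusted p = 0.388 with an estimated correlation). Cell division genes (199) had 0.19 (adjusted p = 0.388 with an estimated correlation), with histone H2B.1 (Nitab4.5_0009487g0010) at 25.5 ± 6.44 and 9.43 ± 1.16 FPKM. The glandular trichome markers had -0.51 with 12 of 13 lower (adjusted p = 0.112 with an estimated correlation), among them phylloplanin-like (Nitab4.5_0000493g0080), an antifungal protein of the leaf surface, at 2.05 ± 1.02 and 7.38 ± 6.25 FPKM (-1.20 ± 0.50; -0.61 without T1 replicate 3 and -1.85 without T1 replicate 2). Phloem markers (44) had 0.20 with 31 higher (adjusted p = 0.425 with an estimated correlation), and 0.04 without T1 replicate 2 to 0.36 without T4 replicate 1. The photosystem median was -0.23 without T1 replicate 1 and -0.24 without T4 replicate 3, the trichome median -0.79 and -0.77 in the same fits, and the pathogenesis-related one 0.20 without T1 replicate 2. Without a filter on low values the trichome median was -0.18, the pathogenesis-related one 0.10, the phosphate starvation one 0.18, the cell division one 0.08 and the phloem one 0.11. Camera called 18 lists, 9 up and 9 down.

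The first nitrogen step, from none to 60 kg, had snakin-2 among the genes with the smallest p. Snakin-2 differed by 1.40 ± 0.32 (SE, n = 3), the metal-binding protein Nitab4.5_0002366g0070 by 1.40 ± 0.25 and the tRNA-splicing subunit Sen2-1-like (Nitab4.5_0021870g0020) by 0.81 ± 0.18. Lower were the auxin receptor AFB2 (Nitab4.5_0002727g0060; -1.53 ± 0.30) and both XERICO genes, Nitab4.5_0011678g0020 with 52.9 ± 18.1 FPKM in T1 and 22.2 ± 3.87 in T2 and Nitab4.5_0001229g0050 with 32.9 ± 9.62 and 13.3 ± 4.23. All 6 had an adjusted p of 0.999. Limma called 0 genes for T2 against T1, with 1120 at an unadjusted p under 0.05 (761 higher, 359 lower) and 0 past the threshold by voom, which had 1111 at an unadjusted p under 0.05. Groups did not overlap for 7.53% of genes, against 10% by chance. Photosystem genes had a median of -0.52 with 147 of 154 lower (adjusted p = 0.408 with an estimated correlation), among them chlorophyll a-b binding protein P4 (Nitab4.5_0007189g0010; 47.3 ± 15.6 and 19.8 ± 7.27 FPKM). The organelle-encoded and ribosomal RNA markers had -0.10 with 26 of 43 lower (adjusted p = 0.715 with an estimated correlation), and -0.0054 without T2 replicate 2. Camera did not call them without T2 replicate 2, T1 replicate 3 or the 2 shallowest libraries. Chlorophyll synthesis genes had -0.32, cytokinin genes -0.14 and pathogenesis-related genes 0.26 (each with adjusted p = 0.4 with an estimated correlation). Among the last, PR protein R minor form (Nitab4.5_0004097g0050) had 226 ± 53.2 FPKM in T1 and 472 ± 163 in T2. WRKY factors (108), transcription factors of defence, had 0.22 with 86 higher (adjusted p = 0.715 with an estimated correlation), among them WRKY43 (Nitab4.5_0007375g0020; 0.82 ± 0.20). Without T2 replicate 2 the medians were -0.32 for photosystem, -0.19 for chlorophyll synthesis, 0.07 for WRKY and 0.15 for pathogenesis-related genes. Without T1 replicate 1 they were -0.33 for photosystem, 0.15 for WRKY and 0.16 for pathogenesis-related genes, and without T1 replicate 3 they were 0.35 for WRKY and 0.40 for pathogenesis-related genes. WRKY genes had 0.35 without T2 replicate 3 and cytokinin genes -0.25 without T1 replicate 2. Without a filter on low values the medians were 0.12 for pathogenesis-related, 0.14 for WRKY and -0.05 for cytokinin genes. With principal component 1 as a covariate they were -0.26 for photosystem, 0.16 for pathogenesis-related and 0.08 for WRKY genes. Camera called 13 lists, 5 up and 8 down.

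Calls against the shared standard level had 0 genes in common, since each of the 3 comparisons had 0 calls. Across genes, which are not independent replicates, the log2 differences of T1 and T2 from T3 had a covariance of 0.031, where a simulation of unchanged groups sharing T3 gave 0.066. For T1 and T4 the covariance was 0.043, and for T2 and T4 0.030, with 0.066 simulated for each. The simulation drew each gene independently, while genes of these libraries move together, so no conclusion is drawn from the difference. Group means rose at every nitrogen step for 7.11% of genes and fell at every step for 4.61%, where random order gives 4.17% for each. Over all genes the median log2 difference was -0.065 for T1 against T3, and the median slope 0.034 over the dose range. Without T1 replicate 1 they were -0.0040 and -0.026, and with quantile normalization 0.0029 and -0.015. A trend with nitrogen cannot be told apart from such a shift of all genes in these shares.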

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

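The library weights, voom, the principal component 1 covariate and the fits without the 2 shallowest libraries were chosen after seeing the data. The count of genes called with the dose, 10 as reported, was 0 without a filter on low values, 0 with quantile normalization, 0 with the replicate block, 0 without the 2 shallowest libraries, 0 with the dose as a rank, 1 without a mean-variance trend, 2 with median-ratio scaling, 5 with voom and 25 with principal component 1 as a covariate. It was 10 with a pseudocount of 0.1, 8 in TPM, 11 with a filter of 5 FPKM and 13 with library weights. Leaving out 1 library gave 0 to 11. All 10 genes kept a positive slope in the fits with limma on log values, which says little, since they were picked for their rise in the same libraries. Without a filter more genes share the adjustment (47216 against 34369). That alone is too small a change to raise the smallest adjusted p from 0.0414 to 0.151. The cause was not tested for any of these settings.

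Excess against no nitrogen had 0 genes as reported, 26 with principal component 1 as a covariate (96.2% higher) and 0 to 6 when 1 library was left out. The F-test had 1 gene with that covariate and 0 to 1 without 1 library. The gene counts of the other 4 pairwise comparisons, and the overlap of calls, were 0 in each alternative run. With an estimated correlation the lists called fell to 0 for each of the 5 comparisons and for the dose. Lists for deficient against standard, 4 as reported, were 2 with quantile normalization, 7 without the 2 shallowest libraries and 4 to 12 without 1 library. Lists for excess against standard, 14 as reported, were 3 to 16 without 1 library, with 3 without T4 replicate 1. The replicate block changed the dose count to 0 and changed no other count of genes. The cause was not tested.

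Several values near 0 reversed. The dose slope of asparagine synthetase (Nitab4.5_0000102g0010, nitrogen dose) was -0.015 without T1 replicate 2, -0.042 without T2 replicate 1, -0.047 without T3 replicate 3 and -0.036 without T4 replicate 2, and up to 0.292 without T1 replicate 1. That of NRT3.1-like (Nitab4.5_0008037g0060, nitrogen dose) was 0.011 without T1 replicate 2 and 0.0022 without T4 replicate 3, and as low as -0.384 without T4 replicate 2. The median of the nitrogen assimilation list (nitrogen assimilation list, median log2 change, nitrogen dose) was 0.027 without the 2 shallowest libraries, 0.0069 without T2 replicate 2 and 0.013 with voom, and ran from -0.055 to 0.039 (without T4 replicate 2) when 1 library was left out. Camera's direction for this list (nitrogen assimilation list, camera, nitrogen dose), coded 1 for up, was 1 with a pseudocount of 0.1, in TPM, with quantile normalization, with the replicate block, without the 2 shallowest libraries, and without T1 replicate 1, T3 replicate 1 or T4 replicate 2. For deficient against standard (photosystems and light harvesting list, median log2 change, deficient against standard), the median was -0.106 without the 2 shallowest libraries, -0.106 without T2 replicate 3 and -0.087 without T3 replicate 1, and up to 0.287 without T3 replicate 2. Camera's direction for it (photosystems and light harvesting list, camera, deficient against standard), coded -1 for down, was -1 in the same 3 fits. For excess against standard (photosystems and light harvesting list, camera, excess against standard) it was -1 without T3 replicate 1. The cause was not tested. Without a filter on low values several list medians shrank: pathogenesis-related genes to 0.093 for the dose and 0.097 for excess against no nitrogen, phosphate starvation genes to 0.179 and 0.180, glandular trichome markers to -0.147 and -0.175 and, for excess against standard, to -0.020, cell wall expansion for excess against standard to 0.064 and nitrate transport for the dose to 0.0079. Dropping the filter adds genes with an FPKM of at least 1 in fewer than 3 libraries. Such genes are under 1 FPKM in most libraries, which may pull a list median toward 0 whatever their change with nitrogen. A gene that is high in the remaining libraries can still differ on this scale. The added genes were not examined by themselves, so the fall of these medians stays unexplained. Genes under 1 FPKM also rest on few reads in T4 replicate 2, with 12347143 in all.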

Other observations

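Clock genes differed between libraries of the same nitrogen level. The test of depth among libraries of like depth, the test of splits for the pairwise gene counts and for the F-test, the count over all lists, the principal component 1 covariate, and the comparisons with random gene sets and across the gap below were chosen after the results were seen. The morning gene LHY (Nitab4.5_0005359g0030), a core factor of the plant clock, ran from 41.7 to 139 FPKM over the 12 libraries, and its copy Nitab4.5_0007792g0010 from 53.6 to 156. The evening gene GIGANTEA, which links the clock to flowering and starch, ran the other way: Nitab4.5_0005673g0010 had 5.41 to 16.0 FPKM and Nitab4.5_0000099g0200 had 4.16 to 14.9. Labels give no sampling times.

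Photosystem genes differed between libraries of the same nitrogen level. Their mean log2(FPKM + 1) ran from 6.13 to 7.46, with an SD of 0.38 within levels. The SD of the 4 level means was 0.257, where means of 3 libraries with no effect of the level give 0.22. Thinning every library to the shallowest depth left an SD 99.0% of that before (0.376) and moved no library mean by more than 0.0128. This argues against the number of reads alone as the cause for these genes. It says nothing on other differences between shallow and deep libraries. Among the 9 libraries with at least 80% of the deepest total of their level the SD was 0.417, or 110% of that over all 12, which argues against sequencing depth as the whole cause. Replicate number took 2.21% of the variance within levels, and 8.33% of the 216 possible numberings took less (the highest took 96.8%), which argues against a field block carried by that number. Time of day at sampling may contribute: morning minus evening clock genes (2 and 16) correlated with the photosystem means as deviations from the level means, with a Pearson r of 0.882 (permutation p = 0.00473), a Spearman rho of 0.832 (permutation p = 0.0062) and r 0.862 without the 2 libraries farthest on the clock measure. This met the condition set beforehand, an r of at least 0.6 in size with p under 0.05, but 37.3% of 100000 random gene sets matched on expression also reached 0.6, so meeting that part says little. An r as far from 0 was reached by 4.996% of the sets. The clock measure also left a gap between 5 libraries (up to 2.65) and 7 libraries (from 3.49), and within the 7 the r was 0.561 (exact permutation p = 0.187), so the relation rests in part on the gap. Whether time of day or another condition that moves many genes together lies behind it cannot be told apart with these libraries. No biological explanation was tested, and a difference between plots in leaf age or light stays open.

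Pathogenesis-related genes had a median dose slope of 0.306 over the range, with an adjusted p of 0.0887 at the estimated correlation. In 4 of 100 random splits of the libraries over the doses, the real one included, this median was as far from 0 (highest other 0.387), but the list was picked from 40 after its slope was seen. Counting that choice, 40 of the 100 had some list as far from 0 in SD of its own draws (2.15, highest other 3.07), so chance is not excluded. Other lists lay farther from 0 by this measure with the real doses. They were pollen and flower markers (2.54), nicotine and alkaloid synthesis genes (2.40, median slope 0.38), glandular trichome markers (2.20) and phosphate starvation genes (2.17). Scaling is argued against as the whole cause (0.265 at the lowest, 86.6%, with quantile normalization). With principal component 1 as a covariate the median was 0.255 (83.5%). The doses had a correlation in size of only 0.16 with that component, so this fit could hardly have removed the slope. Their correlation with component 2 was 0.533, and that axis was not tested as a covariate. The median was 0.204 without T1 replicate 2. It was 0.093 without a filter on low values, where the added genes were under 1 FPKM in most libraries. A rise of defence transcripts with nitrogen supply stays open beside chance. An infection that spread more in well-fed plots stays open, as does shared reading between PR-1 copies, which were not tested.

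The count of 10 genes with the dose was reached in 3 of 100 assignments, the real one included. This share is under 0.05, but with 100 draws its 95% exact binomial interval (counting error only) runs from 0.00623 to 0.0852, so chance is not firmly excluded. Where the count fell to 0, as with the replicate block, quantile normalization, no filter on low values or 8 of the 12 fits without 1 library, any assignment reaches it and the test says nothing. The highest other assignment called 681 genes, another called 252 and 93 called 0, which points to a structure among the libraries. That structure is not principal component 1 alone (looked at after the counts were seen). The doses had a correlation in size with it of 0.829 for 681 genes and 0.548 for 252, but of 0.758, 0.663 and 0.647 in 3 assignments that called 0, and of 0.16 for the real doses. With component 2 it was 0.108 for 681 genes, 0.397 for 252 and 0.533 for the real doses, but 0.720 in 1 assignment that called 0. The 15 lists for the dose were reached in 13 of 100 (highest other 19, median 11), so chance is not excluded for them. The F-test count of 0 is reached by any assignment, 100 of 100, and so tests nothing (highest other 251).

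For the pairwise comparisons, the 10 splits of 6 libraries are too few for a share under 0.05. A gene count of 0 is reached by all 10 splits whatever the data, and the highest other counts were 16 genes for no nitrogen against standard, 1 for deficient against standard and 0 for excess against standard, excess against no nitrogen and deficient against no nitrogen. For lists, no nitrogen against standard had 15 and the highest other split 14 (1 of 10 splits as many). Deficient against standard had 4 and 14 (10 of 10), excess against standard 14 and 19 (3 of 10), excess against no nitrogen 18 and 16 (1 of 10), and deficient against no nitrogen 13 and 17 (4 of 10). The split with 16 genes set T1 replicates 1 and 2 and T3 replicate 2, which lie below 0 on principal component 1, against the other 3 libraries, which lie above 0.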
